A study of Homo sapiens with 6 samples.

How the data were processed

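Chromatin immunoprecipitation with sequencing (ChIP-seq) was performed on THP-1, an established human acute myeloid leukaemia cell line with monocytic features, after 48 hours in DMSO (the solvent control) or in OPA1. OPA1 is the submitters' name for the added compound, not the mitochondrial gene of that symbol, and nothing more is said of it here. There were 6 libraries, with 1 library per group: an EGR1 ChIP, a TET2 ChIP and an input library (sheared chromatin without antibody) for each treatment. EGR1 is a zinc-finger transcription factor of the immediate early class. TET2 is a dioxygenase that oxidises 5-methylcytosine and is often mutated in myeloid leukaemia.

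The deposited files hold 1 list of peaks per ChIP library, called on that library alone against the input of the same treatment with MACS 1.4.2, per the file headers. The caller used a p-value cutoff of 1e-05, a band width of 200 bp, a model fold between 10 and 30 and 50 bp tags, kept 1 tag per position and scaled the larger library to the smaller, per the file headers. Bowtie2 2.2.6, HOMER and the GRCh38 (hg38) build are named in the submitters' processing notes; the role of HOMER is not given in the sources used here. Each peak carries a deposited count of tags, which is a raw number without normalization. Each peak also has a deposited score, 10 times the negative log10 of the caller's p-value, and a deposited ratio, the fold enrichment of the peak over its local background. The false discovery rate of each peak was deposited in percent; MACS of this version estimates it by exchanging ChIP and input. Folds, scores and false discovery rates are the values of the authors' peak caller for 1 peak and were used only to describe, rank or filter peaks within their own list.

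Depth was nearly even. After removal of tags at the same position, the headers give 19900311 tags for EGR1 in DMSO, 19835572 for EGR1 in OPA1, 19782924 for TET2 in DMSO and 19779007 for TET2 in OPA1. The inputs held 20075020 tags in DMSO and 20038155 in OPA1. At this depth most peaks rested on few tags, with a median of 9, 9, 9 and 12 tags per peak in these ChIP libraries. The fragment length modelled by the caller was 68, 70, 64 and 76 bp in the same order. Coordinates are 1-based positions of GRCh38 as in the peak lists.

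Peaks of different lists were taken as overlapping when they shared at least 1 bp. Chance overlap was measured with 1000 random placements of each list, keeping each peak's length and chromosome. Placements could fall in assembly gaps and unmappable sequence, so the chance overlaps are somewhat too low. Shares of peaks have Wilson 95% intervals and tag numbers have exact Poisson 95% intervals; both cover counting error only. No test compares DMSO with OPA1, since each group has 1 library, and differences between the treatments have no replicate check.

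Genes came from a RefSeq table of the GRCh38.p14 assembly with 59679 genes on assembled chromosomes, 20037 of them protein-coding. The table gives gene starts and ends without strand, exons or sequence. A gene's start and end below are its lower and upper coordinates, whatever its strand. Peaks were therefore placed within 1000 bp of either gene end, elsewhere in a gene body, or outside genes, in place of promoter, exon, intron and intergenic classes. The random comparison for these shares used 100 placements. A placement in an assembly gap mostly counts as outside genes. The random share outside genes is therefore somewhat too high, and the random shares in and near genes are somewhat too low. Motif, CpG and repeat shares, fixed in the plan, need the genome sequence and were not analysed here. "Promoter" below follows textbook knowledge of PGK1, RNU6-1 and EEF1A1.

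The genes to be named were fixed by rule before the data were examined. Peaks of each factor were split into those of the OPA1 list alone, those of the DMSO list alone and those in both. In each class the 8 peaks with the highest fold in or within 5000 bp of a protein-coding gene, and the 3 with the highest fold anywhere, could be named. The plan's 5000 bp upstream became 5000 bp beyond either end. The rule also allowed up to 8 genes per treatment at peaks common to both factors and every member of a fixed list that had a peak. EGR1, TET2 and the opioid receptor genes were reported in any case. RNU6-1, EEF1A1 and the chromosome 1 segment were chosen after their values were seen.

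The 13 gene lists, fixed at the same time, covered immediate early genes, textbook EGR1 targets, the DNA methylation and TET pathway, opioid receptors and peptides, G protein and cAMP signalling, myeloid transcription factors, monocyte and granulocyte markers, leukaemia drivers and stem cell genes, apoptosis, interferon response, cell cycle, ribosomal and housekeeping genes, and genes of other lineages. They matched 341 of 342 gene names. A gene counted as having a peak when a peak centre lay in its body or within 5000 bp of it. Each list's count was set against 10000 random lists of protein-coding genes matched on gene length in 10 classes. The share of random lists at least as large was adjusted by the Benjamini-Hochberg method over the 52 combinations of list and library, separately for each alternative. These shares describe these libraries, not the conditions. Some list genes with a peak are not reported here by name.

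The overlap and gene list steps were tested on simulated lists. All 100 overlaps planted into a simulated copy of each list were counted, and a planted gene list was exceeded by 0% of random lists in each library. The planted overlaps were slightly shifted copies of simulated peaks. The planted gene list was far richer in genes with a peak than any fixed list. These tests check the counting and do not show that effects of the size seen here would be detected. Alternatives covered the overlap rule, a fold of at least 8, assembled chromosomes only, the gene window and gene type. A peak false discovery rate of at most 5% and a score of at least 100 were added after the data had been seen. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.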

Results

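Binding of EGR1 and TET2 was profiled in THP-1 leukaemia cells kept for 48 hours in DMSO or OPA1, in a study of opioid receptor signalling and TET-dependent DNA demethylation in leukaemia. The data were 4 peak lists, from 1 ChIP library for each of EGR1 and TET2 in each treatment, with 19779007 to 19900311 filtered tags per ChIP library. The inputs of both treatments entered through the peak calls. There was no replicate of any group, so differences between treatments have no replicate check.

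The first comparison asked how many sites each antibody enriched with and without OPA1. The TET2 list held 891 peaks in DMSO and 1687 in OPA1, a ratio of 1.89. The EGR1 list held 513 peaks in DMSO and 515 in OPA1, a ratio of 1.004. Of the 1687 TET2 peaks in OPA1, 1356 (80.4%, Wilson 95% interval 78.4 to 82.2%) had a peak false discovery rate of at most 5%, against 172 of 891 (19.3%, 16.8 to 22.03%) in DMSO. Only 2 EGR1 peaks in DMSO and 4 in OPA1 passed that limit. The limit does not stand for the same score in each list. In TET2 OPA1 a score of 53.3 (at HMCES) gave a rate of 4.36%, and in TET2 DMSO a score of 54.6 (at JUNB) gave 8.59%. These shares are therefore not a like comparison of peak strength between the treatments. At a score of at least 100, 22 TET2 peaks remained in DMSO and 131 in OPA1, and 2 and 3 EGR1 peaks.

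TET2 peaks covered 182795 bp in DMSO and 462859 bp in OPA1 and took 0.0495% and 0.120% of the filtered tags. EGR1 peaks covered 102761 and 110875 bp, with 0.0257% and 0.0268% of the tags. The mean tag density inside peaks was 5.36 tags per 100 bp for TET2 in DMSO, 5.12 for TET2 in OPA1, and 4.97 and 4.798 for EGR1. Of the EGR1 peaks, 92.0% in DMSO and 87.8% in OPA1 held no more than 12 tags, as did 80.1% and 56.0% of the TET2 peaks.

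**Figure D1:**
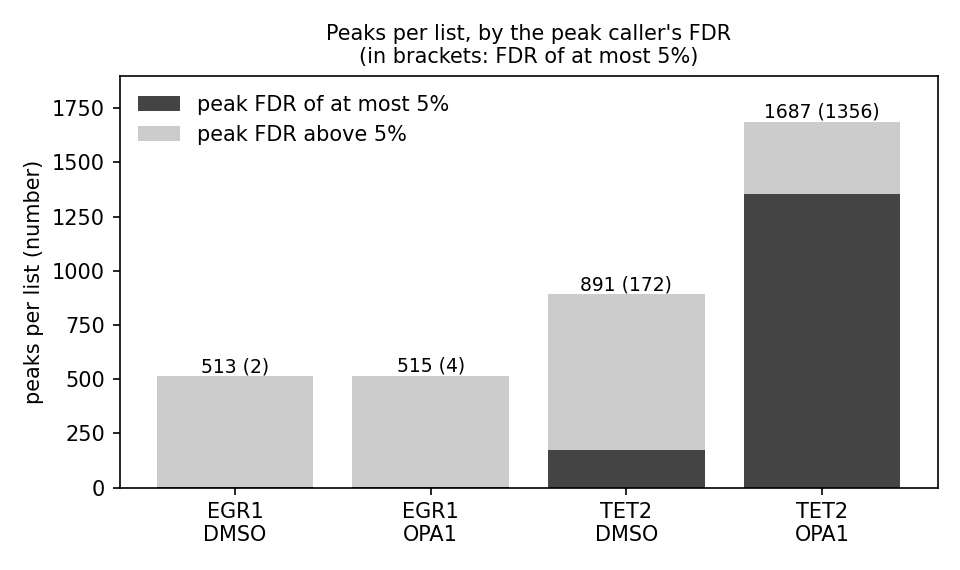
Number of peaks in each of the 4 lists, split by the peak caller's false discovery rate (dark, at most 5%; light, above 5%). The TET2 list in OPA1 holds 1687 peaks, 1356 of them at or below 5%, and both EGR1 lists hold 4 or fewer such peaks.

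The next comparison asked which EGR1 sites differed between DMSO and OPA1. The EGR1 lists shared 2 peaks, at the promoter of PGK1, a glycolytic enzyme, and beside RNU6-1, a U6 small nuclear RNA gene. The PGK1 peak lay at chromosome X, 78103682 to 78104342 in DMSO, across the gene's start at 78104248, and held 172 tags (exact Poisson 95% interval 147 to 200) in DMSO and 98 (79.6 to 119) in OPA1. The RNU6-1 peak lay at chromosome 15, 67840029 to 67840411 in DMSO, at the gene's upper coordinate of 67840045. It held 74 tags (58.1 to 92.9) in DMSO and 17 (9.90 to 27.2) in OPA1. In OPA1 this peak was weak, with a fold of 6.45, a peak false discovery rate of 20.9% and rank 296 by score. The shared peaks were 0.388% (0.107 to 1.405%) of the OPA1 list, while random placement gave a mean of 0.035 shared peaks. The other EGR1 peaks, 513 in OPA1 and 511 in DMSO, were listed in 1 treatment alone. They held a median of 9 tags, near the caller's cutoff, so a peak missing from the other list is not shown to be absent there.

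Peaks listed in OPA1 alone with the highest folds lay in HECW1, a ubiquitin ligase gene (fold 18.5, chromosome 7, 43125285 to 43125468), in DOK6 (18.5) and in SCOC (17.8). They were followed by PIKFYVE, a lipid kinase gene, VPS4B, an ESCRT ATPase gene, RNF150, MYRIP and SFTPD, the surfactant protein D gene, with folds of 16.2 to 16.3. The corresponding peaks in DMSO alone lay in CNTN5, a contactin gene (fold 19.0, chromosome 11, 99643899 to 99644108), in TCEA3 (17.0) and beside TBCB (17.0). They were followed by CSF1R, the receptor of macrophage colony-stimulating factor, PGA5, ARHGAP24, VRK2 and NOL4, each with a fold of 16.6. These peaks held 8 to 14 tags, with peak false discovery rates of 10.0% for PIKFYVE to 44.4% for CSF1R. Outside protein-coding genes, the highest folds in OPA1 alone belonged to peaks starting at 53251236 and 54097343 on chromosome 11 (20.8 and 18.5). They held 9 and 8 tags, each at a peak false discovery rate of 12.5%. The nearest protein-coding gene was OR4C46, at 1351775 and 505674 bp. Repeats at these positions were not analysed. In DMSO alone the highest fold outside protein-coding genes belonged to a peak 46293 bp from FAM209B (19.0). A peak 402537 bp from KCTD8 had a fold of 18.0 in DMSO alone.

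Few genes of the fixed lists carried an EGR1 peak. In OPA1 they were EGR3, EEF1A1, EIF2AK2, MECOM, NFKB1 and PDE4D. In DMSO they were CSF1R, GNAI3 and SPRED1. The EGR3 peak held 17 tags at chromosome 8, 22693403 to 22693797, across the gene's upper coordinate at 22693480. Its fold was 7.98 and its peak false discovery rate 20.9%. The 6 list genes in OPA1 and 3 in DMSO, of 341, compare with means of 3.49 and 3.25 in random lists of the same gene lengths. Of 10000 random lists, 1337 and 6359 held as many. Of the 30 textbook EGR1 targets, CSF1R had a peak in DMSO and none had one in OPA1. No EGR1 peak lay within 5000 bp of EGR1 itself in either treatment.

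An EGR1 peak marked 255 protein-coding genes in DMSO and 260 in OPA1, of which 12 were marked in both. The number of common genes expected by chance was not computed, so 12 is not shown to be low or high. With only 2 DMSO and 4 OPA1 peaks at a peak false discovery rate of at most 5%, the differing genes are not shown to be different EGR1 targets. By position, 6.10% (4.33 to 8.53%) of DMSO peaks and 8.27% (6.17 to 10.99%) of OPA1 peaks lay within 1000 bp of a gene end, inside the ranges of random placement (3.74 to 8.86% and 3.54 to 8.66%). For ends of protein-coding genes alone, the OPA1 share was 4.33%, above the random maximum of 3.94%. Outside genes were 35.2% of DMSO peaks, below the random minimum of 37.4%, and 37.6% of OPA1 peaks, at the random minimum of 37.6%. In gene bodies, over 1000 bp from an end, were 58.7% of DMSO peaks, above the random maximum of 57.1%, and 54.1% of OPA1 peaks, inside the random range. Since placements could fall in assembly gaps, these differences from random placement may be overstated.

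**Figure D2:**
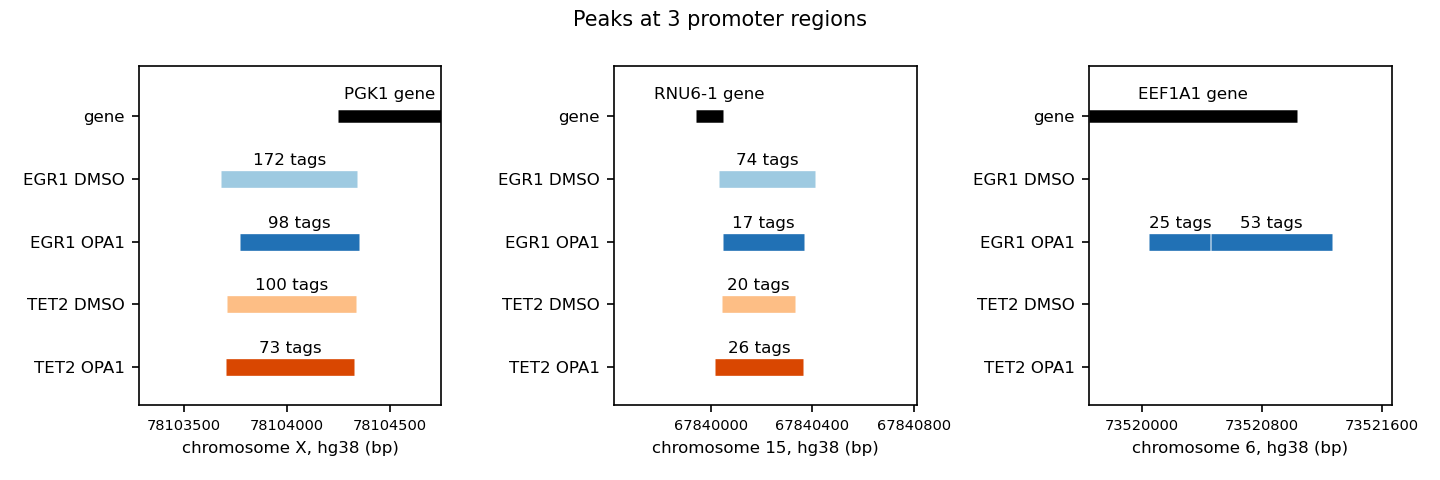
Peaks of each list at the PGK1, RNU6-1 and EEF1A1 genes (x axis, position on GRCh38 in bp; coloured bars, peaks with their tag counts; black bars, genes, cut at the panel edge for PGK1 and EEF1A1). PGK1 and RNU6-1 carry a peak in all 4 lists and EEF1A1 carries 2 adjacent peaks in the EGR1 OPA1 list.

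The TET2 comparison asked where TET2 was enriched with and without OPA1. Peaks common to both treatments included OLFML2A, CUX1, a homeobox factor gene, PGK1, LMO2, a blood-forming adaptor gene, DAZAP2, SIGLEC9, a sialic acid receptor gene of myeloid cells, ACOXL and ADARB1, an RNA-editing enzyme gene. LMO2 had 20 tags (12.2 to 30.9) in DMSO and 37 (26.1 to 51.0) in OPA1 at chromosome 11, 33893690 to 33894046. SIGLEC9 had 24 and 37 tags at chromosome 19, 51127748 to 51128185, ADARB1 14 and 35 at chromosome 21, 45109785 to 45110250, and OLFML2A 13 and 29 at chromosome 9, 124784535 to 124784960. CUX1 had 18 and 22 tags and DAZAP2 19 and 24. PGK1 ran the other way, with 100 tags (81.4 to 122) in DMSO and 73 (57.2 to 91.8) in OPA1, and ACOXL had 18 and 34.

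The TET2 lists shared 171 peaks, 19.2% (16.7 to 21.9%) of the DMSO list and 10.1% (8.79 to 11.7%) of the OPA1 list, where random placement gave a mean of 0.263 and a maximum of 3. Of the DMSO peaks with a peak false discovery rate of at most 5%, 86 of 172 (50%) recurred in OPA1, against 85 of 719 (11.8%) of those above it. Within the 171 pairs, the OPA1 peak held more tags in 152, the same number in 7 and fewer in 12. The OPA1 peaks were also longer in 154 pairs (median 331 against 237 bp), and the tag density was higher in OPA1 in 93 pairs (54.4%, 46.9 to 61.7%).

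**Figure D3:**
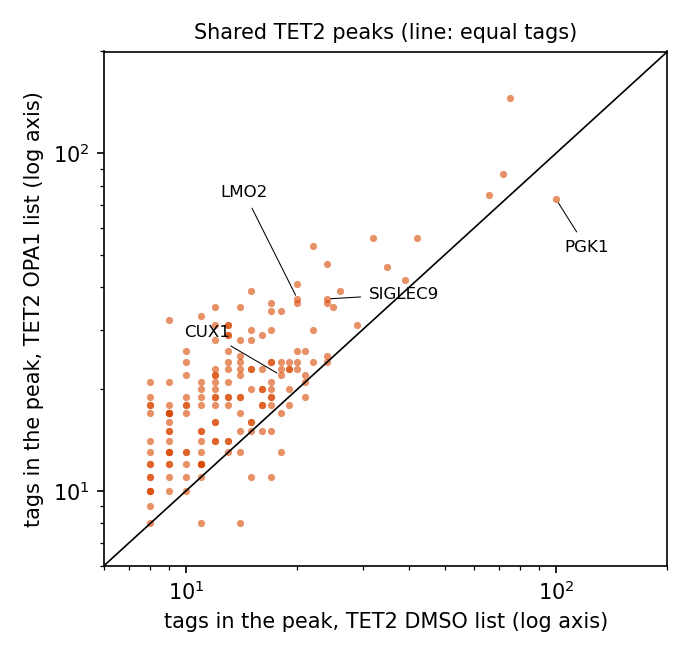
Tags in each of the 171 shared TET2 peaks in DMSO (x axis) and OPA1 (y axis), both on log axes, with the line of equal tags. In 152 pairs the OPA1 value is higher, SIGLEC9, LMO2 and CUX1 among them, and PGK1 lies below the line.

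Among 1516 TET2 peaks in OPA1 alone, the highest folds lay 526 bp from DUS2 (26.7, chromosome 16, 68079722 to 68079970), in ARMC2 (25.3, chromosome 6, 108896161 to 108896478), in COG4 (23.5), in SLC12A3, a sodium chloride cotransporter gene (23.5), and in SMAD7, an inhibitor of TGF-beta signalling (23.3, chromosome 18, 48922914 to 48923201). HSH2D, SHQ1 and EFCAB8 followed with folds of 22.3, 21.9 and 21.7. Far from protein-coding genes, a peak 2038111 bp from PCDH7 had a fold of 25.6. These 9 peaks held 14 to 25 tags. Among 720 TET2 peaks in DMSO alone, the highest folds lay in CFAP58 (27.2, chromosome 10, 104338677 to 104338940) and in CSF1R (25.4, 15 tags, chromosome 5, 150081853 to 150082148). AHNAK and CPNE2 (both 20.3), TNFAIP8L3 (20.1), NFAM1, STON1 and the flank of the growth factor gene TGFB1 (each 17.8) followed, as did a peak on chromosome 20 far from any protein-coding gene (29065044 to 29065260, 22.8).

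OPRM1, the gene of the mu opioid receptor, had a TET2 peak in OPA1 alone, 20 tags (12.2 to 30.9) at chromosome 6, 154169425 to 154169805, inside the gene. In DMSO the nearest TET2 peak lay 10286 bp beyond the gene, with 10 tags. OPRM1 was the only 1 of the 10 opioid receptor and peptide genes with a TET2 peak in OPA1, where random lists averaged 0.405 and 3485 of 10000 held as many. None of the 4 lists held a peak within 5000 bp of OPRD1, OPRK1, OPRL1, EGR1 or TET2.

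Of the 28 genes of the DNA methylation and TET pathway, 5 had a TET2 peak in OPA1: TET1 and TET3, which oxidise 5-methylcytosine as TET2 does, MBD4, a DNA glycosylase gene, HMCES and CXXC5. TET1 had 15 tags at chromosome 10, 68567050 to 68567328, and CXXC5 12 tags at chromosome 5, 139647073 to 139647313, across the gene's start at 139647299; TET3, MBD4 and HMCES had 8 to 10. In DMSO, DNMT3A alone had a peak; the difference between the treatments was not tested, and of all protein-coding genes 2.47% had a TET2 peak in DMSO and 4.65% in OPA1. Random lists averaged 1.12 genes in OPA1 and 38 of 10000 held at least 5 (adjusted share 0.101 over 52 combinations). Counting only peaks within 5000 bp of a gene end, 2 of the 28 genes remained and 773 of 10000 random lists held as many.

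Textbook EGR1 targets carried TET2 peaks in both treatments. HBEGF (8 tags in DMSO and 17 in OPA1) and PDGFB (18 and 13) had them in both, CSF1R and TGFB1 in DMSO, and FLT1 in OPA1. In DMSO 29 of 10000 random lists held at least 4 of 30 (adjusted share 0.101). In OPA1, also with 4 of 30, 335 of 10000 did (adjusted share 0.437). No list had an adjusted share under 0.05 in any library with the lists as deposited. With a peak false discovery rate of at most 5%, a limit chosen after the data had been seen, CSF1R, PDGFB and TGFB1 remained in DMSO and 7 of 10000 random lists held as many (adjusted share 0.0416; 0.0650 to 0.503 under the other alternatives).

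In the remaining lists, genes marked by OPA1 TET2 peaks included the leukaemia and stem cell genes CD34, LMO2, RUNX1T1 and TAL1, the apoptosis genes PMAIP1 and TNFRSF10B, the cell cycle genes CCND3 and E2F1, the signalling genes ADCY7 and PRKAR1A, the monocyte genes ITGB2 and S100A8, and ACTB. In DMSO, TET2 peaks marked HOXA5, LMO2, ITGB2, CSF1R, GNAS and the immediate early genes JUNB and ZFP36. The 28 myeloid transcription factors had no peak in any of the 4 lists, where random lists averaged 0.473 (EGR1 OPA1) to 1.56 (TET2 OPA1) genes, and within 50000 bp 4 of them had a TET2 peak in OPA1. The 28 genes of other lineages had none either, with random means of 0.124 to 0.685. Over all lists, 24 of 341 genes had a TET2 peak in OPA1 against a random mean of 13.0, which 11 of 10000 random lists reached, and 11 had one in DMSO against 6.82, which 766 reached. Random lists were matched on gene length, not on expression.

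TET2 peaks lay near gene ends more often than random placements. Within 1000 bp of a gene end were 9.86% (8.07 to 12.01%) of DMSO peaks and 10.6% (9.25 to 12.2%) of OPA1 peaks, against random maxima of 8.16% and 7.84%. Outside genes were 35.7% and 34.0%, against random means of 42.2% and 41.7%. Placements in assembly gaps may overstate these differences as well. A TET2 peak marked 495 protein-coding genes in DMSO and 931 in OPA1, 153 of them in both.

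The last comparison asked where EGR1 and TET2 peaks coincided in the same treatment. In DMSO they coincided at PGK1, CSF1R and WDR70 among genes. In OPA1 the 8 gene-linked sites with the highest TET2 folds were PGK1, DAZAP2, SIGLEC9, ACOXL, SLC38A1, FOXN3, BCAR3 and ST3GAL1, and TK2, ARHGEF3, EGFLAM and BMP8A were among the other genes. At CSF1R the EGR1 peak (chromosome 5, 150081942 to 150082124, 10 tags) lay inside the TET2 peak, whose centre was 28705 bp from the nearer end of the gene, and neither factor had a peak at this gene in OPA1. At SIGLEC9 in OPA1 the EGR1 peak held 13 tags and the TET2 peak 37, and at SLC38A1 16 and 41. In total 8 of 891 TET2 peaks (0.898%, 0.456 to 1.76%) overlapped an EGR1 peak in DMSO and 24 of 1687 (1.42%, 0.958 to 2.11%) in OPA1, where random placement gave means of 0.066 and 0.127. The order turned with the false discovery limit of 5%: 6 of 172 DMSO (3.49%) and 23 of 1356 OPA1 TET2 peaks (1.70%) overlapped with the limit on the TET2 list, and 2 (1.16%) and 1 (0.0737%) with it on both lists. The limit kept 172 of 891 DMSO and 1356 of 1687 OPA1 TET2 peaks, so this order is between unlike parts of the lists. On both lists it also left only 2 EGR1 DMSO and 4 EGR1 OPA1 peaks to be overlapped. Those shares are bound by the list sizes and cannot order the treatments. Both lists of a treatment were called against the same input, which may add to the excess over random placement. Across treatments, where the inputs differed, 19 DMSO TET2 peaks overlapped OPA1 EGR1 peaks (random mean 0.075). In the other pairing, 6 OPA1 TET2 peaks overlapped DMSO EGR1 peaks (random mean 0.134). These overlaps argue against the shared input library as the source of the whole excess.

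**Figure D4:**
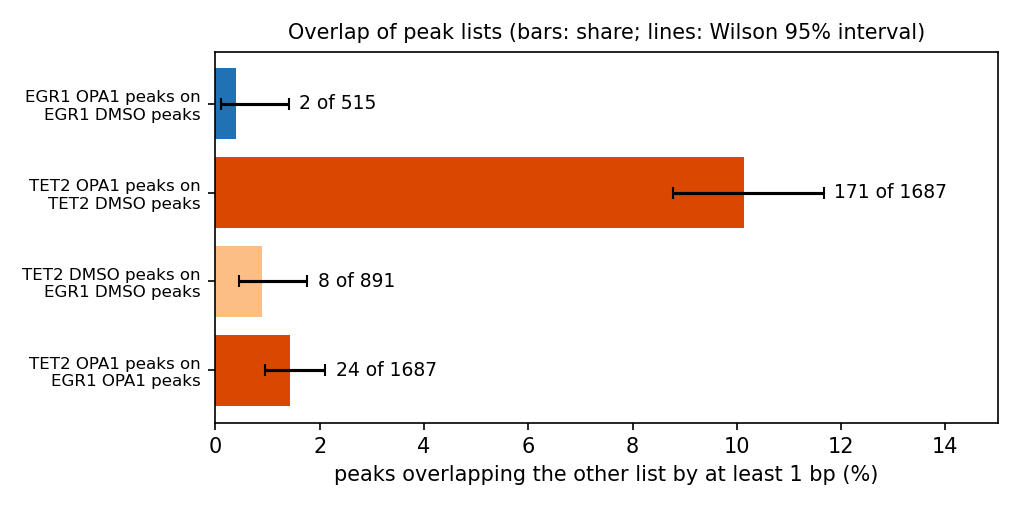
Percentage of peaks of 1 list that overlap a peak of another by at least 1 bp, with Wilson 95% intervals (lines) and counts. The TET2 lists share 171 peaks, against 2 for the EGR1 lists.

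Merging all lists gave 3210 regions found in 1 list, 170 in 2, 16 in 3 and 2 in 4. The regions of all 4 lists were the PGK1 promoter and the RNU6-1 flank. The PGK1 peak had the highest score of every list. Regions in 3 lists included BCAR3, SLC38A1, DAZAP2, TK2, SIGLEC9, ACOXL, ARHGEF3, EGFLAM and ST3GAL1, each with peaks in both TET2 lists and in the OPA1 EGR1 list.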

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

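All tests in this part were chosen after the results were seen.

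The RNU6-1 peak was picked out because its OPA1 minus DMSO tag difference had opposite signs, -57 in the EGR1 libraries and 6 in the TET2 libraries. The TET2 values, 20 tags (12.2 to 30.9) in DMSO and 26 (17.0 to 38.1) in OPA1, overlap within counting error, and the difference between the antibodies was not tested.

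The main comparisons by gene used assembled chromosomes. Unplaced, random or alternate contigs also carried peaks: 5 in the EGR1 DMSO list, 7 in EGR1 OPA1, 9 in TET2 DMSO and 4 in TET2 OPA1.

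The PGK1 and RNU6-1 promoters were the only EGR1 sites found in both treatments. They were taken up for this reason, so their presence in both EGR1 lists was given in advance. A candidate explanation is DNA of an expression vector, since PGK and U6 promoters are common parts of such vectors: all 4 lists as deposited had a peak at both, or 3 with a fold of at least 8 or a peak false discovery rate of at most 5%, which leave out the EGR1 OPA1 peak at RNU6-1, and the EGR1 OPA1 list had adjacent peaks over 1220 bp at the EEF1A1 promoter, also a common vector part. Vector DNA carried by the cells would also be in the inputs against which the peaks were called. The PGK1 folds of 33.3 (TET2 OPA1) to 60.8 (EGR1 DMSO) would therefore need vector DNA mainly in the ChIP libraries. Input tags at these promoters were not examined here. Whether 1 source gave both peaks in a fixed ratio stays open: PGK1 tags were 2.32, 5.76, 5 and 2.81 times RNU6-1 tags in EGR1 DMSO, EGR1 OPA1, TET2 DMSO and TET2 OPA1 (two-sided permutation test, 100000 resamples, p = 0.00266), but this p covers counting error only and the spread between libraries is unknown. Unspecific enrichment of housekeeping and small RNA promoters stays open too. Of 626 other such genes, 2, 4 (0.639%), 5 and 3 had a peak within 1000 bp in the same lists. Random placement gave means of 0.24, 0.3, 0.47 and 1.04 and maxima of 2, 3, 4 and 5. EEF1A1, named above for vector DNA, is among the 4 in EGR1 OPA1, so its peak cannot tell these explanations apart. Binding of EGR1 and TET2 at these promoters was not tested and stays open.

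The growth of the TET2 list in OPA1 was weighed against technical causes. Sequencing depth is argued against, as the TET2 libraries had nearly equal filtered tags (OPA1 0.9998 times DMSO). So is the OPA1 input as the whole cause, since the EGR1 list called against it was 1.004 times as long as in DMSO. A stronger enrichment of the OPA1 TET2 library as a whole could not be decided: 88.9% of shared peaks held more tags in OPA1, but the peaks were longer and the density was higher in only 54.4%. With 1 library per group, an effect of OPA1 on TET2 cannot be told apart from such a difference between immunoprecipitations. The fragment length modelled by the caller also differed, 64 bp in TET2 DMSO and 76 bp in TET2 OPA1. Its part in the longer peaks and the longer list in OPA1 was not tested.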

How the results depend on the processing

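The limits on peak false discovery rate and score were chosen after the data had been seen; all other alternatives were planned. The order below is EGR1 DMSO, EGR1 OPA1, TET2 DMSO, TET2 OPA1 unless stated. Peak numbers stayed within 1.5 times the deposited ones with a fold of at least 8 (479, 478, 837 and 1521) and on assembled chromosomes. With a false discovery rate of at most 5% they were 2, 4, 172 and 1356, the last still within 1.5 times; with a score of at least 100 they were 2, 3, 22 and 131. TET2 had more peaks in OPA1 under each of these.

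Overlap shares stayed inside their intervals under a 50% reciprocal overlap, with centres within 1000 bp and on assembled chromosomes. With a fold of at least 8 in both lists the share of DMSO TET2 peaks found in OPA1 was 16.2%. With a false discovery rate of at most 5% in the list counted, the shared part was 25% of 4 EGR1 OPA1 peaks, 100% of 2 EGR1 DMSO peaks, 11.9% of TET2 OPA1 peaks and 50% of TET2 DMSO peaks, and 3.49% of TET2 DMSO and 1.70% of TET2 OPA1 peaks overlapped EGR1. With that limit in both lists these shares were 25, 50, 6.05 and 47.7%, and 1.16% of TET2 DMSO and 0.0737% of TET2 OPA1 peaks overlapped EGR1. Both reverse the order of the treatments. With the limit in both lists, only 2 EGR1 DMSO and 4 EGR1 OPA1 peaks could be overlapped, so that order is bound by the list sizes. The limit kept 19.3% of TET2 DMSO and 80.4% of TET2 OPA1 peaks. Peaks above it overlapped EGR1 less often in both treatments (0.278% in DMSO, 0.302% in OPA1). The reversed order therefore compares unlike parts of the lists.

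The gene-end share within 5000 bp was 21.9, 25.4, 29.9 and 29.9%, and at protein-coding genes alone 3.35, 4.33, 4.08 and 4.34%. The share outside protein-coding genes was 53.5, 53.3, 51.6 and 49.0%. These follow from the wider window and the fewer genes.

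Genes of the fixed lists with a peak within 5000 bp of a gene end numbered 0 (EGR1 DMSO), 2 (EGR1 OPA1) and 13 (TET2 OPA1), and within 50000 bp of the gene 7 (EGR1 DMSO), 28 (TET2 DMSO) and 51 (TET2 OPA1), as a narrower or wider window gives. With a false discovery rate of at most 5% they were 0, 1 and 5 in EGR1 DMSO, EGR1 OPA1 and TET2 DMSO, as fewer peaks give. Motif, CpG and repeat alternatives were not run, since no sequence was used here. No paired analysis was possible because each group has 1 library. Most peaks of each list held 8 to 12 tags, so their presence or absence in a list lies near the caller's cutoff.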

Other observations

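The segment and the sites below were chosen after their values were seen, and no tests were run on them.

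Peaks with many tags and low folds lay together on chromosome 1 between 39 and 43 Mb, around BMP8A and BMP8B. This segment held 1 of the 3 EGR1 DMSO peaks with at least 35 tags, 3 of 5 in EGR1 OPA1, 6 of 10 in TET2 DMSO and 9 of 33 in TET2 OPA1. The BMP8B region (39799624 to 39801185) had 58 tags in EGR1 OPA1, 75 in TET2 DMSO and 146 in TET2 OPA1. The BMP8A region (39509227 to 39509990) had 38, 42 and 56. The local background implied by tags, length and fold was 3.18 to 3.35 times the median elsewhere in the same list.

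Regions found in 3 lists also lay outside protein-coding genes. Near ELOVL6, a fatty acid elongase gene, there were 11, 9 and 15 tags in EGR1 OPA1, TET2 DMSO and TET2 OPA1. Near WRN, a DNA helicase gene, there were 12, 13 and 24. A region 54617 bp from PDHX held 12 in TET2 DMSO and 19 in TET2 OPA1. The PDHX region was the only region in exactly 3 lists with an EGR1 peak in DMSO (14 tags) and none in OPA1.

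Few tRNA and small nuclear RNA genes other than RNU6-1 had a peak within 1000 bp. Of 598, there were 2 in EGR1 DMSO, 3 in EGR1 OPA1, 5 in TET2 DMSO and 3 in TET2 OPA1, with RNVU1-27 in both TET2 lists. Of 28 ribosomal protein and housekeeping genes, EEF1A1 had one in EGR1 OPA1, and no other list had any at this distance.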
